A study of Mus musculus with 4 samples.

How the data were processed

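Single-cell 3' RNA libraries of CD3+CD4+GFP+ cells from liver and spleen of MC38-bearing female FoxP3-GFP mice were analysed, 1 library per organ and treatment, with 4 libraries in all. Per the labels, 10x Genomics immune profiling chemistry v1.0 and v1.1 was used, without saying which library had which, and biological replicates were pooled before each library. The number of animals is not given. The deposited matrices hold counts, UMIs per gene and barcode for 32285 genes, as a filtered matrix of barcodes called as cells and as an unfiltered matrix of all barcodes with a count. The submitters' processing notes name Cell Ranger 6.1.2 and genome build mm10, and the headers of the unfiltered files name Cell Ranger 4. The values were checked to be whole numbers, and filtered and unfiltered matrices held the same counts for the same barcodes.

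Cells of the filtered matrices were kept with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs. Below the UMI limit were 1464 barcodes in liver anti-PD-1, 1270 in liver isotype, 481 in spleen anti-PD-1 and 457 in spleen isotype, and above the mitochondrial limit 2118, 1581, 670 and 650. In the same order 5582, 5187, 4782 and 4322 passed. Doublet scores came from Scrublet in scanpy 1.11.5, and the highest scores were left out at a rate of 0.8% per 1000 cells, 249, 215, 183 and 149 cells. Scrublet's automatic threshold, not used here, marked 3, 2, 3 and 1. The libraries were clustered together without integration on 2000 variable genes, without Itgb1 and without mitochondrial, ribosomal, T cell receptor and immunoglobulin genes, with 30 principal components, 15 neighbours and a Leiden resolution of 0.8. Clusters with under 60% of cells carrying a Cd3d, Cd3e or Cd3g UMI, or under 20% a Foxp3 UMI, were left out, which removed 458, 327, 188 and 174 cells. The rest are the kept Tregs, and their clusters are called "X-like" from marker genes fixed in advance. Cluster sizes are given where, outside the cluster, fewer than 2 of its 10 leading genes differed by 1.5-fold between the libraries compared, which left no organ comparison and left out clusters 1, 6 and 10. With 1 library per group, a cluster mostly of 1 library may be that library rather than a cell type.

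UMIs were summed over the kept Tregs of each library and scaled to the library's total as CPM. Counts have exact Poisson 95% intervals, ratios of plain CPM exact conditional binomial 95% intervals, and shares of cells exact Clopper-Pearson 95% intervals. Differences of shares have approximate 95% intervals combined from the Wilson limits of both shares. Those of gene list medians, and of Itgb1 ratios under other clusterings, come from counts resampled as Poisson. Log2 ratios add 1 CPM to each value, except those of Itgb1, which are of plain CPM. For shares of cells with a UMI, each cell was thinned at random to 2000 UMIs, and 426, 519, 147 and 101 shallower cells were left out. Free RNA was measured in barcodes outside the filtered list with at most 100 UMIs. UMIs outside the filtered barcodes made up 17.5%, 18.9%, 14.04% and 13.2% of each library. Median UMIs per kept cell were 6139, 5167, 5393 and 4876, and mitochondrial genes took 2.82%, 2.56%, 3.18% and 3.38% of kept UMIs.

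Named genes were chosen by a rule of size fixed before the data were examined, as were the comparisons, gene lists, markers and most alternatives. A gene needed 50 CPM in 1 library of the comparison, and mitochondrial, ribosomal, T cell receptor and immunoglobulin genes were left out. Eligible were the 12 highest and 12 lowest log2 ratios for treatment in each organ, the 12 highest and 12 lowest of the smaller of both organ ratios among genes of the same sign, and the 6 highest and 6 lowest differences between organs of the treatment ratios. For the Itgb1 test they were the 12 highest and 12 lowest log2 folds among genes past the threshold with the same sign in 4 of 4 libraries. To these came Itgb1, Foxp3, Pdcd1, Il2ra and Ctla4, and up to 4 members of each gene list by the size of their ratio with at least 20 CPM. A gene over 3 times as high in empty droplets as in cells is named apart. Of the 62 genes that the rule takes past the threshold of the Itgb1 test, 49 are named, and counts of calls that ended under alternatives are over all 62. Which of the eligible genes to name was settled after the data had been seen. The genes that lead a cluster are named as its description and not as results.

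Of 21 gene lists, a member counted as measured with at least 10 CPM in 1 library of the comparison, and a list with at least 3 measured members was described by its median log2 ratio, its members at least 1.5-fold higher or lower, and the percentile of its median among 10000 random lists of the same size matched on expression in 20 bins. The percentile describes these libraries and is no test. The lists are core Treg, resting and central, effector and activated, ST2 tissue-repair, Th1-like, integrin subunits, cytoskeletal and S100, suppressive molecules, checkpoint receptors, TNF receptor and CD28 family costimulation, chemokine and homing receptors, follicular, RORgt-type, immediate-early, heat shock, interferon response, proliferation, glycolysis, oxidative phosphorylation, cholesterol and fatty acid, and MHC class II. Tested on simulated data with a planted log2 ratio of 0.58, a list's median was recovered at 0.57 to 0.59 in 5 draws, outside the central range of random lists in 5 of 5, and 2 of 60 other lists lay outside it. Both simulated libraries were Poisson draws from the same pooled liver profile, so genes outside the planted list differed by counting error alone. How often an unrelated list lies outside the range in the real libraries is not known from this.

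Cells with and without an Itgb1 UMI at 2000 UMIs were summed per library, which gave 8 sums of thinned counts, from 1080, 743, 824 and 662 cells with a UMI and 3369, 3383, 3440 and 3236 without. The sums were compared with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood F test, library as block, Itgb1 left out) in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05. The libraries that serve as replicates come from different organs and treatments. SE is the standard error of the log2 fold. Gene lists were tested with camera (limma 3.58.1) with its preset correlation and with an estimated one. On simulated data of this size the test recovered 80% of 100 genes with a 2-fold difference and 51% of 100 with a 1.41-fold difference, and 9 of its 140 calls were false.

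Alternatives were all barcodes, stricter quality limits, doublets kept, cells with a Foxp3 UMI only, TMM or DESeq2 1.42.0 size factors, equal weight for each cell, subtraction of 10% free RNA, thinning to other depths, another thinning seed, at least 2 Itgb1 UMIs, a pseudocount of 5 CPM, other limits for measured members, the mean in place of the median, and other clustering resolutions and seeds. In the alternative called the same cluster shares, both libraries were averaged over clusters with 1 set of weights. Of the genes compared, only Itgb1 was kept out of the clustering. For genes and lists that set the clusters apart, a ratio nearer 0 is thus partly built in. The same holds for calls of such genes in the Itgb1 test that are lost when cells are drawn to the same cluster shares. For the Itgb1 test they were DESeq2, no library block, no TMM, no low-count filter, thinning to 1000 or 3000 UMIs, an adjusted p under 0.01, cells without a UMI drawn to the same cluster shares, and each library left out in turn. Leaving out the low-UMI cluster, and the same cluster shares under other clusterings for Itgb1 in liver, were added after the data had been seen. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9. The linear algebra kernel was fixed, since the call of 1 gene by DESeq2 changed with it. Gene positions are those of GENCODE vM21.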

Results

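The series profiled single regulatory T cells (Tregs), the Foxp3-expressing CD4 T cells that restrain immune responses, from female FoxP3-GFP reporter mice with MC38 colon carcinoma grown in the liver. On day 7 of tumour growth the mice received 200 µg of anti-PD-1, an antibody against the inhibitory receptor PD-1, or of an IgG2b isotype antibody, and liver and spleen were taken 3 days later. Cells sorted as CD3+CD4+GFP+ gave 4 droplet libraries, with 1 library in each of the groups liver anti-PD-1, liver isotype, spleen anti-PD-1 and spleen isotype. Animals were pooled within a library, so the treatment and organ comparisons have no replicates and were not tested. Both values are given for each share and for most named genes of these comparisons. Some genes are named with a difference of log2 ratios or a direction alone. Intervals in these comparisons, where given, cover counting error only. Those of counts, plain CPM ratios and shares are exact Poisson or binomial ones. The labels name chemistry v1.0 and v1.1 without saying which library had which, so no comparison could be made within a chemistry. The filtered matrices held 8153 barcodes with 49185800 UMIs (unique molecular identifiers, each 1 captured RNA molecule) for liver anti-PD-1 and 7248 with 36192317 for liver isotype. They held 5537 barcodes with 34124581 UMIs for spleen anti-PD-1 and 5034 with 28262261 for spleen isotype. The Tregs kept for analysis numbered 4875, 4645, 4411 and 3999 in the same order, 17930 in all, with 38393668, 29260006, 29751963 and 24621510 UMIs.

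Foxp3 (chromosome X, 7573644 to 7595245, mm10), the factor that defines Tregs, stood at 67.02 CPM (UMIs of the gene scaled to the library's total) in liver anti-PD-1, 70.3 in liver isotype, 77.2 in spleen anti-PD-1 and 88.99 in spleen isotype. At an equal depth of 2000 UMIs per cell, 14.1%, 13.5%, 14.5% and 15.5% of cells had a Foxp3 UMI, against 1.86% in the B-like cells of a cluster left out under limits that include the share with a Foxp3 UMI, so that this contrast is partly fixed by the filter. Il2ra, the high-affinity IL-2 receptor chain (chromosome 2, 11642807 to 11693193), stood at 179.9, 176, 175 and 184 CPM. Its spleen log2 ratio of -0.073 was 0.078 under the same cluster shares. Of the UMIs of kept cells, 25.6%, 25.4%, 30.4% and 31.9% were of ribosomal genes and 2.11%, 2.91%, 2.43% and 2.83% of Malat1, a nuclear RNA, for which CPM were not adjusted. Among marker genes of other cell types, the summed CPM of 8 B cell genes was 26.1, 23.4, 30.5 and 33.2. That of 10 hepatocyte genes was 28.8, 25.9, 2.86 and 2.27. The 5 CD8 T cell genes summed to 1428, 1817, 467 and 440.0 CPM, of which Ccl5, also on the Th1-like list, took 1406, 1795, 454 and 426. Hemoglobin and other erythroid genes stood at 1006, 1074, 331 and 34.9 CPM. They stood at 5293, 4159.8, 486 and 440.3 CPM in empty droplets.

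The series title concerns Tregs that carry CD29, the integrin β1 chain, in the liver on checkpoint inhibitor therapy, so Itgb1 (ENSMUSG00000025809, chromosome 8, 128685654 to 128733200), the gene for that chain, was compared first. Itgb1 was higher with anti-PD-1 in liver Tregs, at 193 CPM (95% counting interval 188 to 197) against 139.6 CPM (95% counting interval 135 to 144) with isotype, a ratio of 1.38-fold (95% counting interval 1.33 to 1.43). In spleen Tregs it stood at 151 against 135 CPM, a ratio of 1.12-fold (95% counting interval 1.07 to 1.17). At an equal depth of 2000 UMIs, 24.3% (1080 of 4449, 95% exact binomial interval 23.02 to 25.6) of liver Tregs had an Itgb1 UMI with anti-PD-1 and 18.01% (743 of 4126, 95% exact binomial interval 16.8 to 19.2) with isotype. The difference was 6.27 percentage points (95% interval 4.54 to 7.98). In spleen the shares were 19.3% (824 of 4264, 95% exact binomial interval 18.1 to 20.5) and 16.98% (662 of 3898, 95% exact binomial interval 15.8 to 18.2), and the difference was 2.34 points (95% interval 0.666 to 4.01). With another thinning seed the difference was 6.65 points (95% interval 4.92 to 8.36) in liver and 1.15 points (95% interval -0.516 to 2.82) in spleen. In spleen it was 1.101 points (95% interval -0.795 to 2.99) at 3000 UMIs and 0.689 points (95% interval -0.922 to 2.29) over all barcodes, so whether the spleen shares differed depended on the draw, the depth and the cells kept. Without thinning the shares were 44.8%, 33.9%, 37.2% and 33.5%. B-like cells gave 3.35% at the same depth (9 of 269 cells, median of 3985.5 UMIs before thinning, against 6139, 5167, 5393 and 4876 in the kept Tregs). Itgb1 RNA of their own could not be told apart from free RNA, so this share is no measure of free RNA alone. Their Itgb1 level ran from 18.7 CPM in spleen isotype to 40.5 in liver anti-PD-1. A kept cluster, cluster 12, stood at 33.1 and 25.4 CPM in spleen anti-PD-1 and isotype. Given the same cluster shares in both libraries, the log2 ratio of Itgb1 was 0.16 in liver, against 0.47 as measured, and -0.037 in spleen, against 0.16. With other clusterings of the same cells the liver value was 0.13 at a resolution of 1.2 and 0.12 and 0.12 with other seeds. It was 0.44 at a resolution of 0.4, where the main clustering's cluster of highest Itgb1 level did not stand apart. Among cells with a Foxp3 UMI the share of spleen cells with an Itgb1 UMI differed by -0.755 points (95% interval -3.61 to 2.08), so no direction was found there.

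**Figure D1:**
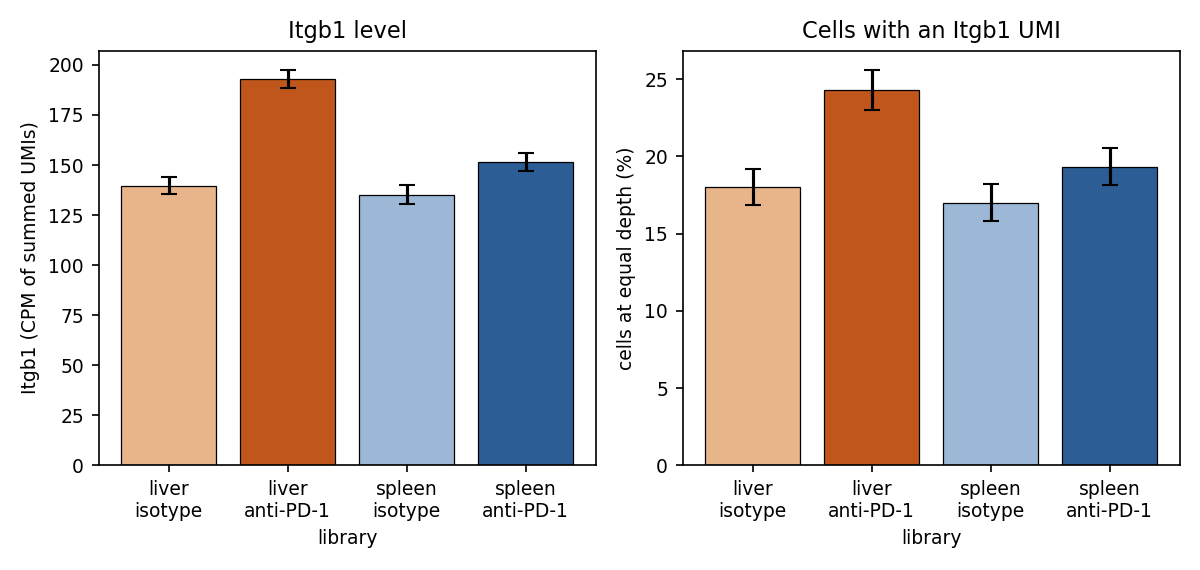
Itgb1 in the kept Tregs of the 4 libraries, as CPM of summed UMIs with exact Poisson 95% intervals (left) and as the percent of cells with an Itgb1 UMI after thinning to 2000 UMIs with exact binomial 95% intervals (right), 1 library per bar. Liver anti-PD-1 was highest on both scales, at 193 CPM and 24.3%.

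Clusters of Tregs, made without Itgb1 among the clustering genes, differed in size between treatments. Cluster 5, led by Itgb1, Il1rl1 (the IL-33 receptor), Emb, Il18r1 and Rora, was left without a cell type name. It made up 12.1% (588 of 4875, 95% exact binomial interval 11.2 to 13.01) of liver Tregs with anti-PD-1 and 6.07% (282 of 4645, 95% exact binomial interval 5.40 to 6.80) with isotype. In spleen it made up 8.34% (368 of 4411, 95% exact binomial interval 7.54 to 9.20) and 5.35% (214 of 3999, 95% exact binomial interval 4.67 to 6.09). Itgb1 within cluster 5 stood at 579.7 CPM in liver anti-PD-1, 668 in liver isotype, 499 in spleen anti-PD-1 and 476 in spleen isotype. Interferon-responsive-like cells (cluster 8, led by Ifit3, Plac8 and Ifit1) made up 17.2% (838 of 4875, 95% exact binomial interval 16.1 to 18.3) of liver Tregs with anti-PD-1 and 10.6% (491 of 4645, 95% exact binomial interval 9.70 to 11.5) with isotype. Th1-like cells (cluster 7, led by Ccl5, Ccr2, Fgl2 and Klrg1, with Cxcr3) made up 23.7% (1156 of 4875, 95% exact binomial interval 22.5 to 24.9) and 34.98% (1625 of 4645, 95% exact binomial interval 33.6 to 36.4). Their Itgb1 stood at 166 and 108 CPM. In spleen, resting-like cells of cluster 3, led by Evl, Bcl2 and Tcf7, made up 20.2% (891 of 4411, 95% exact binomial interval 19.02 to 21.4) with anti-PD-1 and 22.7% (906 of 3999, 95% exact binomial interval 21.4 to 23.99) with isotype. In liver, cluster 3 made up 2.63% (128 of 4875, 95% exact binomial interval 2.20 to 3.11) with anti-PD-1 and 1.55% (72 of 4645, 95% exact binomial interval 1.21 to 1.95) with isotype, the opposite direction to spleen for this cluster. Clusters 10 and 12 also had 8 of 8 resting markers at least 1.5-fold higher. The sizes of cluster 10 in either organ and of cluster 12 in spleen could not be compared. No direction for resting-like cells as a whole is therefore given. Follicular-like cells of cluster 2, with Cxcr5 among its leading genes, made up 1.27% (62 of 4875, 95% exact binomial interval 0.976 to 1.63) of liver Tregs with anti-PD-1 and 0.710% (33 of 4645, 95% exact binomial interval 0.490 to 0.996) with isotype. In spleen they made up 16.3% (721 of 4411, 95% exact binomial interval 15.3 to 17.5) and 16.9% (677 of 3999, 95% exact binomial interval 15.8 to 18.1), with overlapping intervals. A low-UMI cluster (cluster 9, median of 1745.5 UMIs) made up 10.4% (509 of 4875, 95% exact binomial interval 9.60 to 11.3) and 13.2% (613 of 4645, 95% exact binomial interval 12.2 to 14.2) of liver Tregs. The difference for cluster 5 in liver was 5.99 points, and 9.21 and 9.45 points for the cluster of highest Itgb1 level under other clustering seeds. Those clusters were larger, with 62.7% and 63.9% of their cells from cluster 5. At a clustering resolution of 0.4 cluster 5 did not stand apart, and the cluster of highest Itgb1 level was another one.

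**Figure D2:**
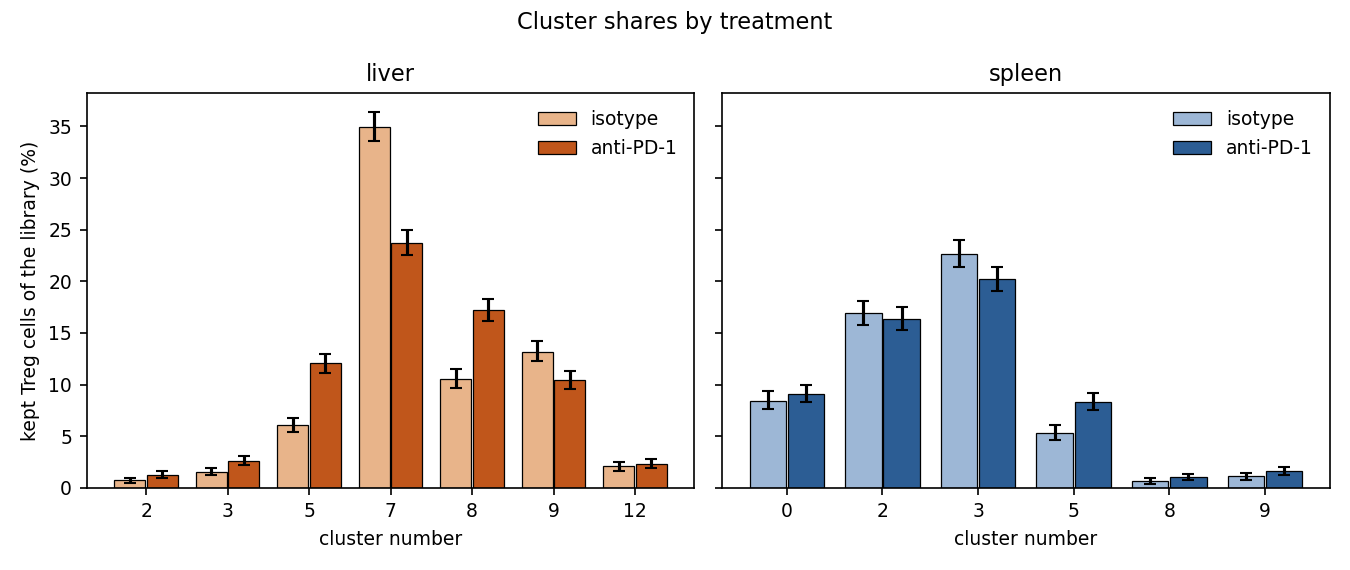
Percent of each library's kept Tregs in the clusters whose sizes could be compared between treatments, with exact binomial 95% intervals, for liver (left) and spleen (right). In liver, cluster 5 stood at 12.1% with anti-PD-1 and 6.07% with isotype, and cluster 7 at 23.7% and 34.98%.

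In liver Tregs, cell-cycle genes and the chemokine genes Ccl3 and Ccl4 were higher with anti-PD-1 than with isotype, and immediate-early genes were lower. Ccl4, which encodes a chemoattractant of T cells and monocytes, stood at 433 against 200.1 CPM, 2.16-fold (95% counting interval 2.10 to 2.23), and Ccl3 at 76.8 against 43.8. Il18r1, a chain of the IL-18 receptor, stood at 51.1 against 30.6 CPM, 1.67-fold, and the lactate exporter gene Slc16a3 was 1.62-fold higher (57.2 against 35.3 CPM). Asb2, a subunit of a ubiquitin ligase, was the lowest of the named genes, at 34.4 against 71.7 CPM, 2.09-fold (95% counting interval 1.95 to 2.24) lower. Fosb, Jun and Fos, whose products form the AP-1 factor after stimulation or stress, were 1.98-fold (142 against 281 CPM), 1.95-fold (309 against 602) and 1.72-fold (235 against 404) lower.

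By gene list, all 24 measured proliferation genes were higher with anti-PD-1 in liver and 13 were at least 1.5-fold higher, with a median log2 ratio of 0.64 (95% counting interval 0.59 to 0.67). That was the 100th percentile of 10000 random lists of matched expression. The median was 0.077 under the same cluster shares. Examples are the linker histone gene Hist1h1b (2.14-fold, 189.6 against 88.4 CPM), the mitotic ubiquitin-conjugating enzyme gene Ube2c (2.09-fold, 85.4 against 40.9), Birc5 (1.91-fold, 82.8 against 43.4) and Stmn1 (1.77-fold, 221 against 125). Pclaf, at 1.61-fold (112 against 69.6 CPM), had a log2 ratio of -0.048 under the same cluster shares. Hist1h1b, Birc5, Stmn1 and Pclaf are among the leading genes of cluster 6, and such genes were not set aside for the clustering. The fall of these genes and of the list under the same cluster shares is thus partly built in. Of 16 cytoskeletal and S100 genes, which mark memory T cells, 13 were higher and 2 at least 1.5-fold so (Anxa2 at 186 against 122 CPM, 1.53-fold, and Lgals3 at 167 against 111, 1.51-fold), with a median of 0.23. Of 23 interferon response genes, 20 were higher, 2 at least 1.5-fold so (Ifit1 at 128 against 82.1 CPM, 1.56-fold, and Rsad2 at 43.9 against 28.7, 1.53-fold), with a median of 0.24. Under the same cluster shares the medians were 0.12 for the cytoskeletal and 0.094 for the interferon list. The 6 measured follicular genes had a median of 0.25 (0.16 with the same cluster shares), with Cd200 at 26.8 against 20.3 CPM, 1.32-fold. Pdcd1, the gene of PD-1 itself (chromosome 1, 94038305 to 94052553), stood at 114 against 87.2 CPM, 1.31-fold (95% counting interval 1.24 to 1.37). Of 19 immediate-early genes, 17 were lower and 4 at least 1.5-fold so (Fosb, Jun, Fos and Dusp1), with a median of -0.34 (95% counting interval -0.39 to -0.32), the 0th percentile, and of -0.26 under the same cluster shares. In the cells of the left-out clusters 11, 13 and 14 the same list had a median of -0.37.

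Genes for the suppressive products of Tregs had a median of -0.23 (95% counting interval -0.27 to -0.20) in liver with anti-PD-1, with 9 of 14 lower, and of -0.21 under the same cluster shares. Ebi3, a subunit of the suppressive cytokine IL-35, at 10.97 against 20.3 CPM, was 1.85-fold (95% counting interval 1.63 to 2.11) lower and Il10, at 139 against 183, 1.31-fold lower. Areg, an epidermal growth factor family ligand, was 1.35-fold lower (47.3 against 63.9 CPM), but had a log2 ratio of 0.063 among cells with a Foxp3 UMI. Ctla4, which competes with CD28 for its ligands (chromosome 1, 60887000 to 60915832), stood at 613 against 747 CPM, 1.22-fold lower. The checkpoint receptor list had a median of -0.17 (8 of 12 lower). Median log2 ratios were -0.13 for the ST2 tissue-repair list, -0.11 for effector genes, -0.097 for costimulatory receptors of the TNF receptor and CD28 families, -0.087 for core Treg genes and -0.084 for Th1-like genes. They were -0.077 for the 11 measured integrin subunits (but 0.036 under the same cluster shares and 0.014 as a mean), -0.032 for chemokine and homing receptors and 0.0065 for resting and central genes. They were 0.096 for heat shock genes, 0.094 for glycolysis, 0.078 for oxidative phosphorylation and 0.048 for cholesterol and fatty acid genes. Given the same cluster shares, the medians were -0.16 for checkpoint receptors, -0.090 for the ST2 tissue-repair list, -0.049 for effector genes, -0.031 for costimulatory receptors, -0.0074 for core Treg genes and -0.057 for Th1-like genes. On that basis they were -0.00089 for chemokine and homing receptors, 0.14 for resting and central genes, 0.067 for heat shock genes, 0.033 for glycolysis, 0.0045 for oxidative phosphorylation and 0.042 for cholesterol and fatty acid genes. Of the remaining alternatives, those that moved a median outside its counting interval and by at least 2-fold or past 0 follow. Means in place of medians were -0.054 for checkpoint and -0.046 for costimulatory receptors. Over all barcodes the medians were -0.18 for Th1-like genes and -0.095 for chemokine and homing receptors. Among cells with a Foxp3 UMI they were -0.035 for the ST2 tissue-repair list, -0.048 for costimulatory receptors, 0.086 for chemokine and homing receptors and 0.15 for resting and central genes, which stood at 0.13 with members of at least 50 CPM. Of the other integrin subunits named, Itgb8 was at 1.18 and Itgav at 0.853 times its isotype level (64.1 against 54.4 and 114 against 134 CPM). Fewer than 3 genes of the RORgt-type and MHC class II lists were measured in liver, with Maf at 0.755 (472 against 625 CPM) and Cd74 at 0.809 times its isotype level (122 against 151 CPM), or a log2 ratio of 0.10 over all filtered barcodes.

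In spleen Tregs, immediate-early and heat shock genes were higher with anti-PD-1 than with isotype, along with cell-cycle genes, Ccl4 and Il10. Fos stood at 230.2 against 95.97 CPM, 2.40-fold (95% counting interval 2.29 to 2.51), Fosb was 2.31-fold higher (223 against 96.8) and Hsph1, a co-chaperone, 2.39-fold higher (151 against 62.95). Ccl4 stood at 65.8 against 31.1 CPM, 2.12-fold, and Lgals3, the gene of galectin-3, at 67.2 against 32.5. The lowest named genes were closer to 1: Cd96, a receptor of the nectin family, was 1.36-fold lower (46.9 against 63.97 CPM) and Ccr7, which guides cells into lymph nodes, 1.29-fold lower (52.7 against 68.2). Hbb-bs, at 186 against 15.6 CPM, and Hba-a1, at 65.6 against 10.8, had the highest ratios among the eligible genes, those with at least 50 CPM in 1 of the libraries compared. In spleen anti-PD-1, 1 cell held 8663 of the 9807 hemoglobin UMIs.

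By gene list, all 11 heat shock genes were higher in spleen with anti-PD-1, 4 of them at least 1.5-fold, with a median log2 ratio of 0.55 (95% counting interval 0.42 to 0.62), and of 0.56 under the same cluster shares. Of 19 immediate-early genes 16 were higher and 7 at least 1.5-fold so, among them Zfp36 (1.93-fold, 189 against 97.6 CPM) and Jun (1.56-fold, 486 against 311), with a median of 0.42 (95% counting interval 0.39 to 0.45). In the cells of the left-out clusters 11, 13 and 14 the immediate-early list had a median of 0.72. Of 23 proliferation genes 22 were higher and 8 at least 1.5-fold so, with Hist1h1b at 1.80-fold (114 against 63.2 CPM) and a median of 0.46, which became 0.028 under the same cluster shares. All 10 ST2 tissue-repair genes were higher, with Il10 at 1.99-fold (25.5 against 12.8 CPM) and a median of 0.35. The effector list had a median of 0.29 (15 of 16 higher, with Itgae, the integrin chain of tissue-resident T cells, at 1.54-fold and 47.9 against 31.2 CPM). The cytoskeletal list had a median of 0.34 and the interferon list of 0.24 (18 of 20 higher, none by 1.5-fold). The suppressive list had a median of 0.22, and Ctla4 stood at 257 against 196 CPM, 1.31-fold (95% counting interval 1.27 to 1.36). Under the same cluster shares the medians were 0.39 for the immediate-early, 0.15 for the ST2 tissue-repair, 0.087 for the effector, 0.047 for the cytoskeletal, 0.18 for the interferon and 0.018 for the suppressive list. The resting and central list had a median of -0.19, with 9 of 13 lower, and of 0.095 under the same cluster shares. Pdcd1 stood at 83.6 against 67.9 CPM, 1.23-fold (95% counting interval 1.16 to 1.31). Medians were 0.23 for 3 measured RORgt-type genes, 0.15 for glycolysis, 0.12 for follicular genes, 0.12 for checkpoint receptors, 0.11 for chemokine and homing receptors and 0.11 for Th1-like genes, of which the cytotoxic granule gene Nkg7 was 1.76-fold higher (193 against 109 CPM). The Th1-like median was -0.092 under the same cluster shares. They were 0.077 for cholesterol and fatty acid genes, 0.070 for oxidative phosphorylation, 0.059 for integrin subunits, 0.032 for costimulatory receptors and 0.028 for core Treg genes. Given the same cluster shares, the medians were 0.15 for RORgt-type genes, 0.051 for glycolysis, 0.074 for follicular genes, 0.018 for checkpoint receptors and 0.049 for chemokine and homing receptors. On that basis they were 0.052 for cholesterol and fatty acid genes, 0.000089 for oxidative phosphorylation, 0.012 for integrin subunits, 0.023 for costimulatory receptors and 0.0044 for core Treg genes. By the rule used for liver, the remaining alternatives with a larger effect were as follows. The Th1-like median was 0.40 with members of at least 1 CPM, 0.24 as a mean and 0.23 among cells with a Foxp3 UMI. Costimulatory receptors stood at 0.11 and integrin subunits at 0.16 as means, follicular genes at 0.27 with members of at least 50 CPM and cholesterol and fatty acid genes at -0.011 among cells with a Foxp3 UMI.

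**Figure D3:**
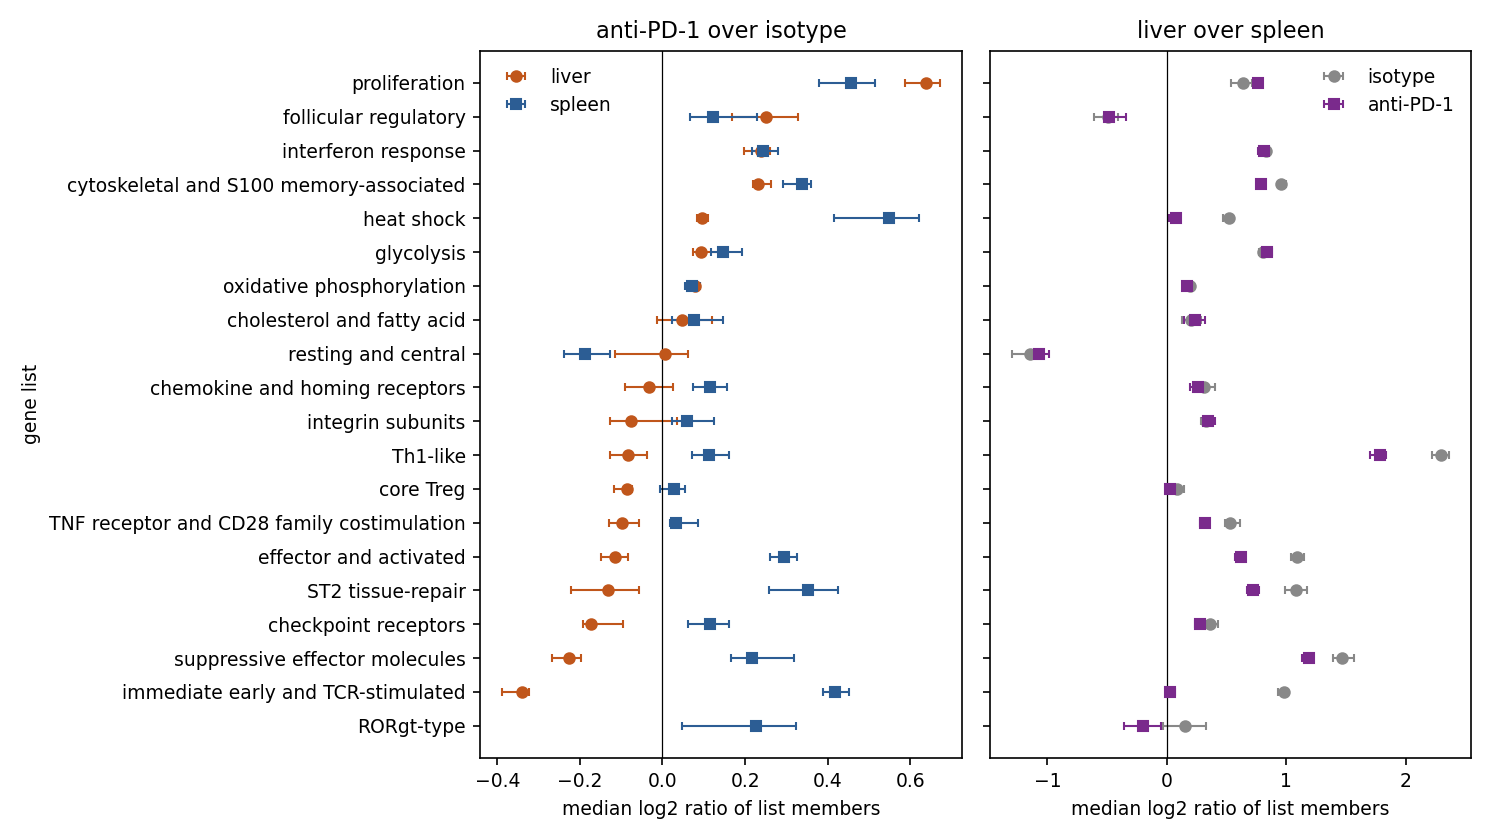
Median log2 ratio of the measured members of each gene list, anti-PD-1 over isotype in liver and spleen (left) and liver over spleen under each treatment (right), with 95% intervals from resampled counts, for lists with at least 3 measured members. The immediate-early list stood at -0.34 in liver and 0.42 in spleen, and the proliferation list at 0.64 and 0.46.

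Liver and spleen Tregs were then compared under each treatment. Effector, Th1-like and interferon response genes were higher in liver, and genes of resting cells were higher in spleen, with either antibody. CPM in parentheses are those of liver against spleen. Plac8 was 14.9-fold (217 against 14.6) higher in liver with isotype and 24.1-fold (263 against 10.9) with anti-PD-1. In the same order Gzmb, the cytotoxic protease granzyme B, was 6.91-fold (360.4 against 52.2) and 6.83-fold (425 against 62.1) higher, and Ccl4 6.44-fold (200.1 against 31.1) and 6.59-fold (433 against 65.8). The interferon-induced Ifit3 was 6.39-fold (76.3 against 11.9) and 6.71-fold (109.9 against 16.4) higher in liver, and Il10 14.2-fold (183 against 12.8) and 5.47-fold (139 against 25.5). In spleen, Id3, an inhibitor of E-protein transcription factors, was 8.63-fold (16.3 against 140.4) higher with isotype and 5.65-fold (21.02 against 119) with anti-PD-1. Likewise the survival gene Bcl2 was 3.68-fold (44.5 against 164) and 4.03-fold (32.8 against 132) higher in spleen, and Tcf7, a factor of resting T cells, 3.76-fold (44.1 against 166) and 2.63-fold (53.3 against 140.2). Tcf7 had liver over spleen log2 ratios, under the same cluster shares, of 0.21 and 0.21. The sizes of those clusters could not be compared between organs. Cluster 3, with Tcf7 among its leading genes, had 72 and 128 liver cells with isotype and anti-PD-1, against 906 and 891 spleen cells. Itgb1 was close between organs with isotype, at a liver over spleen ratio of 1.03-fold (95% counting interval 0.986 to 1.08), a difference not detectable at this depth, and 1.27-fold (95% counting interval 1.23 to 1.32) with anti-PD-1. With isotype its log2 ratio was 0.047, but 0.14 in thinned cells and -0.039 among cells with a Foxp3 UMI.

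By gene list, 8 of 10 Th1-like genes were at least 1.5-fold higher in liver under each treatment, with median log2 ratios of 2.30 with isotype and 1.79 with anti-PD-1 and Nkg7 at 5.88 and 4.50-fold (641 against 109 and 867 against 193 CPM). The medians were 1.47 and 1.19 for suppressive molecules, with Ctla4 at 3.82 and 2.38-fold. They were 1.09 and 0.62 for effector genes (all 16 higher in liver under each treatment), 1.09 and 0.72 for ST2 tissue-repair genes and 0.96 and 0.79 for cytoskeletal and S100 genes. They were 0.83 and 0.81 for interferon response genes and 0.81 and 0.84 for glycolysis. Proliferation genes stood at 0.64 and 0.76, which became -0.091 and -0.032 under the same cluster shares. Under the same cluster shares the medians with isotype and anti-PD-1 were 0.81 and 0.70 for Th1-like genes, 0.68 and 0.58 for suppressive molecules and 0.27 and 0.15 for effector genes. They were 0.059 and 0.23 for ST2 tissue-repair genes, 0.090 and 0.18 for cytoskeletal and S100 genes, 0.036 and 0.022 for interferon response genes and 0.47 and 0.53 for glycolysis. These weights run over clusters whose sizes could not be compared between organs, some with few cells in 1 organ. Cluster 8 had 25 and 45 spleen cells with isotype and anti-PD-1, against 491 and 838 liver cells. The values therefore do not show that the organs are alike at equal cluster make-up. All 13 resting and central genes were lower in liver, 12 of them at least 1.5-fold, with medians of -1.14 and -1.07, and 0.029 and -0.13 under the same cluster shares. The follicular list had medians of -0.49 and -0.48. Immediate-early genes stood at 0.98 with isotype and 0.029 with anti-PD-1 (0.76 and 0.23 under the same cluster shares), and heat shock genes at 0.52 and 0.075. Medians were 0.53 and 0.32 for costimulatory receptors, 0.36 and 0.28 for checkpoint receptors and 0.33 and 0.35 for integrin subunits. They were 0.31 and 0.26 for chemokine and homing receptors and 0.089 and 0.029 for core Treg genes. They were 0.19 and 0.17 for oxidative phosphorylation, 0.20 and 0.24 for cholesterol and fatty acid genes and 0.15 and -0.20 for 3 RORgt-type genes. For these lists too the medians were taken with the same cluster shares, and with isotype and anti-PD-1 they were -0.032 and -0.16 for follicular genes, 0.40 and 0.051 for heat shock genes, 0.069 and 0.019 for costimulatory receptors, 0.079 and 0.062 for checkpoint receptors and 0.16 and 0.13 for integrin subunits. They were 0.18 and 0.20 for chemokine and homing receptors, 0.059 and 0.096 for core Treg genes, 0.00087 and -0.031 for oxidative phosphorylation, 0.097 and 0.042 for cholesterol and fatty acid genes and 0.16 and -0.13 for RORgt-type genes. By the rule used for liver, the remaining alternatives moved the following medians. With members of at least 50 CPM the medians with isotype and anti-PD-1 were 0.045 and 0.10 for follicular genes and 0.063 and -0.047 for chemokine and homing receptors. With anti-PD-1, checkpoint receptors stood at 0.039 over all barcodes and 0.12 with members of at least 1 CPM, and chemokine and homing receptors at 0.0029 over all barcodes. Core Treg genes stood at 0.33 and 0.20 as means, 0.037 and -0.020 among cells with a Foxp3 UMI, 0.0082 and -0.010 without the low-UMI cluster and, with anti-PD-1, -0.025 over all barcodes. Immediate-early genes with anti-PD-1 stood at 0.11 as a mean, 0.16 with members of at least 50 CPM, 0.16 over all barcodes and -0.010 with free RNA subtracted. RORgt-type genes stood at -0.091 with isotype as a mean and -0.049 with anti-PD-1 with members of at least 1 CPM. The median over all genes of at least 50 CPM was 0.12 and 0.092. The hemoglobin gene Hba-a2, over 3 times as high in empty droplets as in cells of the liver libraries, was 47.1-fold (186 against 3.94 CPM) and 3.66-fold (156 against 42.7) higher in liver, and most hemoglobin UMIs of the kept cells lay in 1% of them.

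To ask which genes go with Itgb1 within a library, cells with an Itgb1 UMI at 2000 UMIs were compared with cells without one, with the 4 libraries as replicates (n = 4) and Itgb1 itself left out. The classes were set after thinning, so the cells without a UMI include some that had one before it. In liver anti-PD-1, 2184 of 4875 cells had an Itgb1 UMI before thinning and 1080 of 4449 after it. Cells with an Itgb1 UMI had more RNA of Nrp1, a semaphorin co-receptor on Tregs, at 205 against 103 CPM (log2 fold ± SE 1.0004 ± 0.065, adjusted p = 5.09e-10). They also had more of the cell-cycle phosphatase gene Cdc25b (1.05 ± 0.097, adjusted p = 2.46e-07) and of the IL-18 and IL-33 receptor genes Il18r1 (0.92 ± 0.089, adjusted p = 4.27e-07) and Il1rl1 (1.02 ± 0.14, adjusted p = 3.05e-05). Each was higher in 4 of 4 libraries. They had less RNA of Plac8 (-1.43 ± 0.15, adjusted p = 1.17e-06), Il10 (-1.07 ± 0.12, adjusted p = 2.09e-06), Il2ra (-0.58 ± 0.074, adjusted p = 1.87e-05) and Bcl2 (-0.74 ± 0.081, adjusted p = 2.09e-06), each higher in 0 of 4 libraries. Plac8 and Il10 were low in spleen. With anti-PD-1, Plac8 stood at 82.5 against 337 CPM in liver and 5.94 against 10.6 in spleen, and with isotype at 117 against 224 and 10.3 against 14.5. Il10 stood at 58.4 against 162 and 14.8 against 22.4 with anti-PD-1, and at 105 against 191 and 6.61 against 8.81 with isotype. By edgeR's quasi-likelihood test with a library block, 219 genes were higher and 189 lower at a Benjamini-Hochberg adjusted p under 0.05, of 10131 tested. Without TMM scaling 329 were higher and 110 lower. Foxp3 and Pdcd1 did not pass, at log2 folds of -0.20 (adjusted p = 0.273) and -0.093 (adjusted p = 0.824). Rora, a factor of tissue Tregs, the adhesion gene Emb, the histone genes Hist1h2ae and Hist1h1b, Cldnd1, Slc4a7, Slamf6, Kif1b and Gprin3 were higher by log2 folds of 0.67 to 0.80. Ly6c1, Penk, Satb1, Chchd10 and Tnfrsf9 were lower, with log2 folds from -1.31 to -0.72. The hemoglobin genes Hbb-bt, Hba-a1, Hba-a2 and Hbb-bs had the lowest log2 folds (-3.11, -2.42, -2.11 and -2.11), and in each library at least 96.2% of hemoglobin UMIs lay in 1% of the cells. At 1000 UMIs per cell they were no longer past the threshold, with log2 folds of -0.62, -0.42, -0.37 and -0.30. The rule for named genes takes 62 genes past the threshold. When cells without an Itgb1 UMI were drawn to the same cluster shares, 33 of the 62 no longer passed, among them Il18r1 (0.34), Il1rl1 (0.13), Il2ra (-0.18) and Bcl2 (-0.13). The same held for Rora (0.26), Hist1h2ae (0.18), Hist1h1b (0.12), Cldnd1 (0.12), Slc4a7 (0.26), Kif1b (0.35), Gprin3 (0.27), Ly6c1 (-0.012) and Chchd10 (-0.23). Nrp1 (0.67), Cdc25b (0.62), Plac8 (-0.64) and Il10 (-0.60) still passed. With 1 library left out, 13 of the 62 no longer passed without liver anti-PD-1, 15 without liver isotype, 14 without spleen anti-PD-1 and 1 without spleen isotype.

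**Figure D4:**
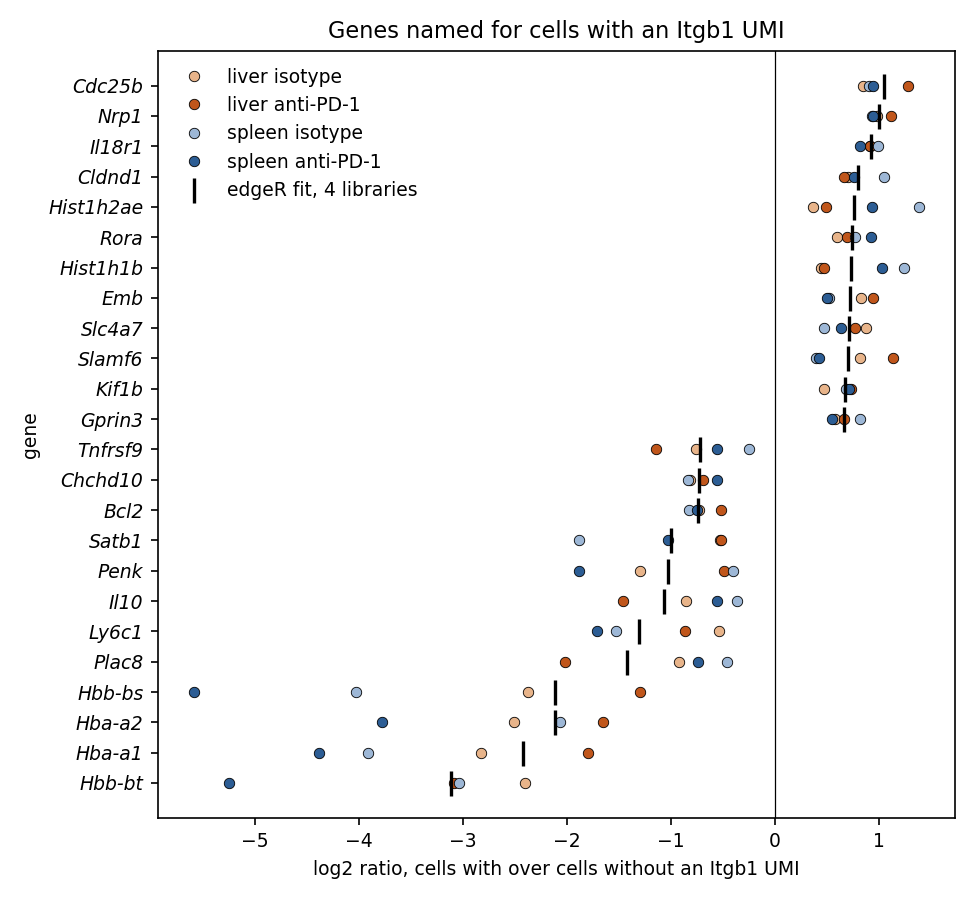
Log2 ratio of CPM in cells with over cells without an Itgb1 UMI for the 12 highest and 12 lowest named genes, with 1 point per library and a bar for the edgeR fit over the 4 libraries. Nrp1 was higher in 4 of 4 libraries, with a fitted log2 fold of 1.0004, and Plac8 higher in 0 of 4, with -1.43.

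By gene list, 15 of 17 cytoskeletal and S100 genes were higher in cells with an Itgb1 UMI and none lower (15 adjusted over the list alone). Among them were Lmna, the gene of lamin A (0.82 ± 0.17, adjusted p = 0.00607), Anxa2 and Lgals3 (log2 folds of 0.66 and 0.63) and Crip1 (0.63 ± 0.058, adjusted p = 2.37e-07). Lmna no longer passed without liver isotype (0.70) or without spleen anti-PD-1 (0.65). With cells without an Itgb1 UMI drawn to the same cluster shares, Lmna (0.20), Anxa2 (0.28) and Lgals3 (0.30) no longer passed. The list had a camera adjusted p = 1.62e-37, and adjusted p = 0.174 with an estimated correlation. Of 24 proliferation genes 13 were higher and none lower (17 higher adjusted over the list alone). Cenpf, Ccnb2 and Ube2c had log2 folds of 1.13, 1.09 and 1.01, and the list had a camera adjusted p = 8.38e-29, and adjusted p = 0.108 with an estimated correlation. Cenpf and Ccnb2 no longer passed with the same cluster shares (0.27 and 0.32), nor Ube2c at 1000 UMIs (0.62), nor Cenpf among cells with a Foxp3 UMI (0.71). No list had an adjusted p under 0.05 with an estimated correlation. Of 16 effector genes 6 were lower and none higher (7 lower and 2 higher over the list alone), among them Gzmb (-0.83 ± 0.14, adjusted p = 0.000583), which was higher in 1 of 4 libraries. Of 14 suppressive molecules 4 were lower and 1 higher (8 lower and 1 higher over the list alone), with Lag3 at -0.87 and Ctla4 at -0.26, each higher in 1 of 4 libraries. Lag3 stood at 84.8 against 232 CPM in liver anti-PD-1 and 78.5 against 189 in liver isotype. In spleen it hardly differed, at 62.9 against 62.2 with anti-PD-1 and 50.7 against 52.5 with isotype. Of 10 Th1-like genes 4 were lower and none higher (6 lower and 1 higher over the list alone), with Nkg7 at -0.67. Camera's adjusted p was 0.000115 for the effector list, 3.24e-06 for the suppressive list and 0.00232 for the Th1-like list. With an estimated correlation it was adjusted p = 0.503, 0.417 and 0.456. Of 12 integrin subunits 3 were higher and 1 lower (4 and 3 over the list alone), with Itga4, the partner of integrin β1 in VLA-4, at a log2 fold of 0.44 (adjusted p = 9.8e-05), Itgb7 at 0.26 and Itgae at -0.47. Itgae was higher in 1 of 4 libraries. Itgb7 no longer passed without liver isotype (0.25), without spleen anti-PD-1 (0.25) or with the same cluster shares (0.10). Core Treg genes gave 1 higher (Nrp1) and 6 lower of 12 (1 and 7 over the list alone), with Tnfrsf4 at -0.50. Resting and central genes gave 2 higher and 5 lower of 13 (3 and 6), with Tcf7 at 0.56 and Satb1 at -0.998. Tcf7 stood at 109 against 49.3 CPM in liver anti-PD-1 and 106 against 48.7 in liver isotype. In spleen it stood at 190 against 156 with anti-PD-1 and 193 against 192 with isotype. At 1000 UMIs Lmna (0.47), Ctla4 (-0.26) and Itgae (-0.46) no longer passed, nor Itgae at 3000 UMIs (-0.35), nor Lmna among cells with a Foxp3 UMI (0.76). Without liver anti-PD-1, Ctla4 (-0.19), Tcf7 (0.38) and Itgae (-0.36) were no longer past the threshold. The same held without liver isotype for Ctla4 (-0.23), Tcf7 (0.42), Itgae (-0.31) and Lag3 (-0.70), and without spleen anti-PD-1 for Ctla4 (-0.27).

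For the other lists the numbers are genes higher, genes lower and, in parentheses, the same over the list alone. Chemokine and homing receptors gave 4 and 3 of 19 (6 and 4), with Ccr4 at a log2 fold of 0.70. ST2 tissue-repair genes gave 2 and 4 of 11 (2 and 4). Follicular genes gave 1 and 2 of 10 (1 and 2), with Sh2d1a at 0.53, checkpoint receptors 0 and 3 of 13 (2 and 3) and costimulatory receptors 0 and 3 of 11 (0 and 6). Interferon response genes gave 0 and 4 of 23 (0 and 7), with Usp18 at -0.49 and Isg15 at -0.40. Usp18 no longer passed without liver anti-PD-1 (-0.29) or liver isotype (-0.55), nor Isg15 without liver anti-PD-1 (-0.17) or spleen anti-PD-1 (-0.40). Immediate-early genes gave 0 and 3 of 19 (0 and 4), with Myc at -0.58, which was 0.050 under the same cluster shares. Myc no longer passed without liver anti-PD-1 (-0.64), spleen anti-PD-1 (-0.55) or spleen isotype (-0.44). Heat shock genes gave 0 and 1 of 11 (0 and 5), the lower gene being Hspe1 (log2 fold -0.29). Without spleen anti-PD-1 it stood at -0.29 and no longer passed. MHC class II genes gave 0 and 1 of 5 (0 and 1), the lower gene being Cd74 (-0.43). With the same cluster shares Ccr4 (0.30), Sh2d1a (0.14), Usp18 (-0.068), Isg15 (-0.085) and Hspe1 (-0.17) no longer passed. At 1000 UMIs Ccr4 (0.57), Usp18 (-0.35) and Myc (-0.81) no longer passed, nor Isg15 at 3000 UMIs (-0.31). Nor did Ccr4 (0.64) and Usp18 (-0.52) among cells with a Foxp3 UMI, or Myc without the low-UMI cluster (-0.54). By edgeR no gene passed of 14 glycolysis, 21 oxidative phosphorylation, 16 cholesterol and fatty acid and 5 RORgt-type genes, also over the lists alone. There were 2, 1, 1 and 1 at an unadjusted p under 0.05 and 0, 0, 0 and 0 by DESeq2. The counts moved with single libraries: 138 genes were higher and 146 lower without liver anti-PD-1, 114 and 93 without liver isotype, and 108 and 76 without spleen anti-PD-1. They were 39 and 85 when cells without an Itgb1 UMI were drawn to the same cluster shares, and 92 and 87 among cells with a Foxp3 UMI. They were 76 and 51 by DESeq2, and 0 and 0 by edgeR without a library block (284 and 175 at an unadjusted p under 0.05).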

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

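Of the tests below, those of cluster make-up in both patterns and of cell depth for Itgb1 were chosen after the result was seen. With 1 library per group, no difference between organs given here was tested. The labels name chemistry v1.0 and v1.1 without saying which library had which, so a difference of chemistry between the libraries compared stays open for every treatment and organ contrast.

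The immediate-early genes, which cells induce within minutes of stimulation or tissue handling, stood out because their list lay below the range of random lists in liver with anti-PD-1 (median log2 ratio -0.34) and above it in spleen (0.42), a liver minus spleen difference of -0.76. Cluster make-up, and free RNA at a share of 10%, were argued against as the whole cause. The difference was -0.64 (95% counting interval -0.68 to -0.60) under the same cluster shares and -0.73 (-0.81 to -0.70) with that share of free RNA subtracted. Handling that acts on every sorted cell predicted the same pattern in cells other than Tregs. The CD8 or NK receptor, B-like and myeloid clusters left out of the analysis showed -1.10 (-1.35 to -0.86), with -0.37 in liver and 0.72 in spleen. That these clusters hold no Tregs was not tested. In the myeloid one, cluster 14, 35.9% of cells had a Cd3 UMI and 6.04% a Foxp3 UMI. The list was also lower in 10 of 11 kept clusters in liver and higher in 10 of 11 in spleen, but heat shock genes, another set induced by stress, were higher in 8 of 11 in liver and in 11 of 11 in spleen and so did not share the opposite directions. Handling that differed between libraries stays a candidate explanation, and an effect of anti-PD-1 on all of these cells stays open, untested.

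Itgb1 in liver Tregs, at a log2 ratio of 0.47 with anti-PD-1 over isotype, was weighed because the series title concerns it. Free RNA at a share of 10% was argued against, since the ratio was 0.45 (95% counting interval 0.39 to 0.52) with that share subtracted. Other shares were not tried. In cells thinned to the same depth the ratio was 0.47 (0.37 to 0.59). CPM are already scaled to the total, so thinning changes little beyond the weight of deep cells and the loss of shallow ones. It therefore cannot decide whether depth played another part. With the same cluster shares 0.16 (0.11 to 0.23) of the log2 ratio remained within clusters, so a larger share of cluster 5 may carry much of the difference but was not shown to carry all of it. At a resolution of 0.4 the value was 0.44, but cluster 5 did not stand apart there, so that value cannot test its share. In clusterings that kept most of cluster 5 in 1 cluster it was 0.13 at a resolution of 1.2 and 0.12 and 0.12 (0.057 to 0.17) with other seeds. Cluster make-up as the whole cause stays open. Whether anti-PD-1 or another difference between the pooled libraries gave it stays open with 1 library per group.

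Other gene lists lay below the range of random lists in liver and above it in spleen with anti-PD-1. The liver minus spleen difference of the median log2 ratio was -0.41 for the effector list (liver -0.11, spleen 0.29), -0.48 for the ST2 tissue-repair list (liver -0.13, spleen 0.35) and -0.44 for the suppressive list (liver -0.23, spleen 0.22). Under the same cluster shares the medians in liver and spleen lay closer, at -0.049 and 0.087 for the effector list, -0.090 and 0.15 for the ST2 tissue-repair list and -0.21 and 0.018 for the suppressive list. Among cells with a Foxp3 UMI the liver median of the ST2 tissue-repair list was -0.035. Against random lists drawn anew under each of these alternatives, the effector list in liver and the suppressive list in spleen under the same cluster shares, and the ST2 list in liver among cells with a Foxp3 UMI, lay within the range, and the other values given lay outside it.

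Named genes stood out where anti-PD-1 and isotype differed in opposite directions in liver and spleen, and these differences between organs were not tested. Higher in liver and lower in spleen with anti-PD-1 were Tubb4b, a β-tubulin gene (difference of log2 ratios 0.65), Ms4a4b (0.58), Chchd10 (0.52), Tcf7 (0.51), the linker histone gene Hist1h1e (0.48) and Clec2d (0.43). Lower in liver and higher in spleen were Fosb (-2.18), Fos (-2.03), Jun (-1.60), Ppp1r15a, a gene of the integrated stress response (-1.52), Klf6 (-1.33), Rgs2 (-1.29) and the hemoglobin gene Hba-a1, in libraries where few cells held most hemoglobin UMIs (-2.81).

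Some clusters were left out of the Treg comparisons because few of their cells carried Cd3 or Foxp3 UMIs, and whether their cells were impurities of the sort was not tested. They were cluster 4 with 124 NK-like cells, cluster 11 with 378 cells led by Klrd1, Klrk1 and Cd8a, cluster 13 with 278 B-like cells led by H2-Aa and Cd79a, and cluster 14 with 298 cells led by S100a9 and Lyz2. Cluster 15 had 13 cells led by Ifitm1, Mcpt8 and other genes, and cluster 16 had 56 cells led by S100a8, Vcam1 and C1qa. Of these, clusters 11, 13 and 14 served for the handling test above, and cluster 13 was set beside the kept Tregs for shares of cells with a UMI.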

How the results depend on the processing

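Leaving out the low-UMI cluster, and the same cluster shares under other clusterings, were chosen after the data had been seen, and the other alternatives before. The same cluster shares and the thinned cells were made tests of an explanation only after their values had been seen. The counting intervals limit what single libraries can show, and with 1 library per group no spread between animals is known. Unless a reason is given, the cause was not tested.

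Itgb1 stayed higher with anti-PD-1 in liver under all 15 alternatives, with log2 ratios outside the counting interval of 0.47 for cells with a Foxp3 UMI (0.40) and the same cluster shares (0.16, or 0.13 at resolution 1.2 and 0.12 and 0.12 with other seeds). In spleen (0.16) it was 0.049 for cells with a Foxp3 UMI and reversed to -0.037 with the same cluster shares. Liver over spleen with isotype (0.047) became 0.14 over all barcodes, -0.039 for cells with a Foxp3 UMI, 0.12 with equal weight per cell, 0.14 in thinned cells and 0.16 with the same cluster shares. With anti-PD-1 (0.35) it became 0.43 with equal weight per cell. The liver difference in the share of cells with an Itgb1 UMI was 10.9 points without thinning, 4.32 at 1000 UMIs and 3.58 for at least 2 UMIs, which count other cells by construction. The spleen difference fell to -0.755 points (95% interval -3.61 to 2.08) among cells with a Foxp3 UMI, an interval that holds 0. The difference in share of the cluster with the highest Itgb1 level was 4.35 points in liver and 1.59 in spleen at resolution 0.4. That cluster was not cluster 5, since 98.5% of its cells came from cluster 6, led by histone genes and Pclaf, whose size could not be compared. The difference was 9.21 and 9.45 points in liver with other seeds.

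Genes higher and lower in cells with an Itgb1 UMI (219 and 189) numbered 329 and 110 without TMM, 92 and 87 among cells with a Foxp3 UMI, and 39 and 85 with the same cluster shares, with fewer cells without a UMI. They numbered 122 and 81 at an adjusted p under 0.01, 76 and 51 by DESeq2, and 0 and 0 by edgeR without a library block (459 at an unadjusted p under 0.05). Lower genes numbered 369 without the low-count filter, with 17986 genes tested, and 122 at 1000 UMIs. With a library left out, higher genes ranged from 108 (without spleen anti-PD-1) to 222 (without spleen isotype) and lower genes from 76 to 230. Without liver anti-PD-1 there were 138 and 146 and without liver isotype 114 and 93. Of the 62 genes that the naming rule takes past the threshold, the call ended for 33 with the same cluster shares, 1 of them in the opposite direction (Myc, -0.58 and 0.050). It ended for 15 at 1000 UMIs, 5 at 3000 UMIs, 9 among cells with a Foxp3 UMI and 2 without the low-UMI cluster. With 1 library left out it ended for 13 without liver anti-PD-1, 15 without liver isotype, 14 without spleen anti-PD-1 and 1 without spleen isotype.

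Of the 785 values of gene list medians under alternatives, 553 lay within the counting interval, 225 moved outside it and 7 reversed, which is a change of sign in a list outside the range of random lists. With the same cluster shares these were the resting and central list in spleen (0.095) and for liver over spleen with isotype (0.029), and the proliferation list for liver over spleen with isotype (-0.091) and anti-PD-1 (-0.032). Among members of at least 50 CPM they were the follicular list for liver over spleen with isotype (0.045) and anti-PD-1 (0.10) and the chemokine and homing receptors with anti-PD-1 (-0.047), which leaves fewer members. Another 14 medians, of lists within that range, changed sign, 10 of them outside the counting interval. Among these were integrin subunits in liver (0.036) and Th1-like genes in spleen (-0.092) with the same cluster shares. Of 553 such values of the named genes, 369 lay within the counting interval, 177 moved outside it and 7 reversed, and 5 others changed sign from a ratio whose interval holds 1. Pclaf in liver (-0.048), Itgb1 and Il2ra in spleen (-0.037 and 0.078) and Tcf7 between organs (0.21 with isotype, 0.21 with anti-PD-1) reversed with the same cluster shares. Areg in liver (0.063) reversed among cells with a Foxp3 UMI and Cd74 in liver (0.10) over all barcodes.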

Other observations

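The test of other splits of the libraries and the genes whose shares of cells are given below were chosen after the data had been seen.

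Cells that share the Itgb1-rich cluster 5 differed in number more than in Itgb1 level. Its Itgb1 stood at 579.7 CPM in liver anti-PD-1 and 668 in liver isotype, while its cell number was 588 against 282. Outside it, Itgb1 in follicular-like cells of cluster 2 stood at 434 and 410.2 CPM in liver, from 62 and 33 cells, and at 155 and 167 in spleen. In Th1-like cells of cluster 7 it stood at 166 CPM in liver anti-PD-1 and 108 in liver isotype, from 1156 and 1625 cells. In the same order it stood at 229 and 190 CPM in cluster 6 and at 39.6 and 56.6 in cluster 10. Within clusters, Itgb1 in liver thus moved in both directions. Cluster 12, with Ly6c1 and Dapl1 but also 4 hemoglobin genes among its 10 leading genes and left without a cell type name, had 74.7 and 32.4 CPM in liver and 33.1 and 25.4 in spleen, and interferon-responsive-like cells of cluster 8 71.2 and 80.4 in liver.

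Shares of cells with a UMI at 2000 UMIs per cell were also taken for 3 genes of Treg states. Klrg1, a receptor of terminally differentiated lymphocytes, was found in 16.9% of liver cells with anti-PD-1 and 21.4% with isotype, and in 7.79% and 6.49% of spleen cells. Mki67, a marker of dividing cells, was found in 11.9% and 7.90% of liver cells and 5.09% and 3.54% of spleen cells, and Isg15, an interferon-induced modifier, in 28.3% and 25.01%, and 19.2% and 14.5%. No share in B-like cells was measured for these genes.

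Most hemoglobin UMIs came from few cells, while 26.2% of the kept cells in liver anti-PD-1, 21.98% in liver isotype, 3.17% in spleen anti-PD-1 and 1.78% in spleen isotype had at least 1. Cells with at least 20 of them numbered 23 in liver anti-PD-1, 16 in liver isotype, 2 in spleen anti-PD-1 and 2 in spleen isotype.

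For the genes that differed between cells with and without an Itgb1 UMI, the 8 sums were split in other ways that part every library's pair. Of the 8 such splits, 1 gave as many genes as the real one, which is the real one itself with 408 genes, and the highest of the others gave 0. With 8 splits the share cannot fall under 0.05. Of the 35 splits of the 8 sums into 4 and 4, 27 part fewer pairs, among which the highest count was 113, and 3 could not be fitted.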
